A study of Mus musculus with 4 samples.

How the data were processed

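Total RNA from the injured cortex of mice was compared on 4 2-colour Agilent mouse arrays, each with 1 knockout-labelled sample in Cy3 and 1 wild-type sample in Cy5. Per the labels' protocols, 200 ng of RNA was labelled per sample with a linear amplification kit; the text of that protocol speaks of plant material and so cannot describe this tissue in full. The groups, the dyes and the replicate numbers 1 to 4 came from the labels. All 4 arrays lay on 1 slide and were scanned together, so slide and scan could not act as batches.

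Per the file headers, the scanner files were made with Agilent Feature Extraction 11.0.1.1, whereas the submitters' processing notes name version 10.7.3.1. The spot and background signals are intensities on a linear scale, per the file headers, and were used as deposited. The log10 ratio of each spot is Cy5 over Cy3 of the processed signals, which were background-subtracted and dye-normalized by that software, per the file headers. The deposited series matrix holds log2 values. For all 39030 probes with a single spot these equalled log2 of the processed Cy5 over Cy3 signal of the same array to within 0.001, so their direction is wild type over knockout, opposite to the one used here. Their column medians were -0.05, -0.06, -0.04 and -0.03, and no further centring was found. The deposited flags are other values, 0 or 1 per the file headers, and mark spots well above background, saturated or non-uniform.

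The files used here held median and no mean spot signals, so the median spot and median local background signals were used in place of the mean signal planned. Background was corrected with normexp (offset 50) and log ratios were normalized within each array by loess, with control spots at weight 0, in limma 3.58.1 (R 4.3.3, statmod 1.5.0). Control spots and the 139 to 186 spots per array marked as outliers were left out, and spots of 1 probe were averaged. A probe was kept when it was well above background on at least 3 of the 4 arrays in either channel, which left 30259 of 39429 probes. Accessions were named through a table of RefSeq genes of the assembly GRCm38.p6, used for names and for which genes lie near each other. In all, 27427 probes (69.6%) received a symbol. The array design is annotated on the build mm9, per the file headers, so no coordinates are printed and distances from Ndrg2 are those of the table's assembly. The probe with the highest mean intensity stood for a gene. The 24565 features tested were 17014 with a symbol and 7551 known only by the array's own name.

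Each feature's log2 ratio of knockout-labelled over wild type was tested against 0 over the 4 arrays with lmFit and eBayes, adjusted by Benjamini-Hochberg, and passed at an adjusted p under 0.05. The array was thereby the block that pairs 2 samples. Where a probe was not well above background in a channel on any array, only a bound is given: the mean of the brighter channel over the mean, per array, of the higher of the dim probe's own signal and the lowest signal among probes well above background, after loess and Aquantile; such bounds are open to dye bias. Gene lists were tested with camera (preset correlation 0.01) over 32 lists that held 838 genes, of which 786 were tested. Genes near Ndrg2 were tested with Fisher's exact test, two-sided.

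The lists, the tests and the rule for named genes were fixed before the data were examined. The rule took Ndrg1 to Ndrg4, the 10 highest and 10 lowest genes among those that passed with the same sign on all 4 arrays (passing over clone, predicted and RIKEN names), up to 3 members with the smallest p in each list, all genes that passed within 2 Mb of Ndrg2, and sex-linked genes. Genes named beyond it are said to be chosen after their values were seen. A gene that this rule selects is not reported here.

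The steps were tested on simulated data with the spread of the 24565 features and 200 changed features. Of 50 features changed by 1.2-fold, 15 were recovered, and of 50 changed by 1.5-fold, 44. Of 50 changed by 2-fold, 47 were recovered, and of 50 by 4-fold, 50, with 7 false calls in all. These simulated data gave 163 calls and the real data 5230, for which the adjustment lets larger p-values pass. The recovery and the false calls therefore need not carry over to the real data. Data with no change gave 0 calls and 0 lists. Each feature was drawn independently, so those 0 lists cannot show how the list test behaves when members of a list move together. In the real data the estimated correlation between members of the interferon-stimulated list was 0.881. Spike-in controls had an observed over expected slope of log ratios of 0.728 to 0.739, with correlations of 0.954 to 0.970, so ratios were compressed, and the software marked the slope as out of its range. Across features, log ratios correlated at 0.73 between arrays 1 and 2, at 0.63 between arrays 3 and 4, and at 0.41 to 0.48 between the other pairs.

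Alternatives were other background corrections, the scanner software's log ratios, median centring, Aquantile and scale normalization, other filters, the mean of all probes of a gene, other variance priors, array weights, the channels as 8 separate samples with no replicate block or with an estimated correlation within spots (0.373), the series matrix values, each array left out, other thresholds, other set tests and other windows. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.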

Results

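Gene expression was measured in the cortex on the injured side of mouse brains, 24 h after the left middle cerebral artery had been closed for good by electrocoagulation, a model of ischaemic stroke. Per the labels, the mice were 8 weeks old, of the strain C57BL/6, and either wild type or knockout for Ndrg2, a gene of the N-myc downstream regulated family that is strongly expressed in astrocytes. The series held 4 2-colour arrays on a single slide. Each array carried 1 wild-type sample labelled with Cy5 and 1 knockout sample of the same replicate number labelled with Cy3. The labels did not say that every sample came from a separate animal, so p-values measured only the spread between these samples, which may in part be technical. Each array had 43020 spots outside the controls, of which 73.6 to 74.9% were well above background in the knockout channel and 76.7 to 79.0% in the wild-type channel, and no spot was saturated. No array had the dyes the other way round, so a dye effect that belonged to a single probe could not be separated from genotype. Changes are given as log2 of knockout over wild type, and the 4 arrays limited their precision.

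The first question was whether the targeted gene itself was lower. Ndrg2 fell by 0.18 ± 0.05 on the log2 scale (SD, n = 4; limma, adjusted p = 0.0249), a 1.13-fold difference seen on all 4 arrays. Its single probe remained far above background in the knockout channel, at 769 times the local background, and brighter there than 98.3% of all probes. The labels did not say which part of the gene was deleted and the probe sequence was not given, so a probe outside the deleted part would check nothing. With median centring in place of loess Ndrg2 stood at -0.81 (adjusted p = 6.71e-06), but 200 features of like intensity not placed on chromosome 14, a comparison chosen after the values were seen, then had a median of -0.65, against -0.02 with loess. Relative to such features, this probe did not show a large loss of Ndrg2 RNA, which a knockout label need not imply. Because the values did not check the genotype, the samples are called knockout-labelled. Of its relatives, Ndrg4 fell by 0.26 ± 0.13 (adjusted p = 0.0205) among very bright features that were lower as a set, with a median of -0.19, Ndrg3 was at -0.13 ± 0.15 and did not pass (adjusted p = 0.178), and Ndrg1 rose by 0.15 ± 0.05 (adjusted p = 0.0440), a direction that turned to -0.25 when arrays were only centred on their median. With the scanner software's own log ratios Ndrg2 stood at -0.04 (adjusted p = 0.529) and Ndrg4 at -0.08, neither past the threshold, and leaving out replicate 1, 2 or 3 also ended the call of Ndrg2.

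The second question was which genes differed between the knockout-labelled and the wild-type cortex after ischaemia. The largest rise belonged to Samd4, which encodes an RNA-binding repressor of translation, at 2.86 ± 0.11 on the log2 scale (SD, n = 4), or 7.24-fold. It was followed by Myh7, a myosin heavy chain of slow muscle and heart, at 1.56 ± 0.26, the kinase gene Stk32c at 1.46 ± 0.36, Xlr3b at 1.38 ± 0.66 and the amino acid transporter gene Slc7a8, higher by 2.29-fold (SD 0.09 on the log2 scale). The largest falls belonged to Rnase4, a secreted ribonuclease, at -1.87 ± 0.07 (3.64-fold), Cdhr1, a cadherin of photoreceptors, at -1.76 ± 0.24, and Mmp3, the protease stromelysin 1, at -1.51 ± 0.87. The death receptor gene Tnfrsf10b fell by 1.23 ± 0.09 and Esm1, an endothelial proteoglycan gene, by 1.11 ± 0.96.

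Of the other genes among the 10 highest, Ldb3, a muscle Z-disc gene, rose by 1.02 ± 0.07 and Acin1 by 0.996 ± 0.11. A second probe of Acin1 stood at 0.54, and a second probe of Ldb3 at 0.09. Plac9a rose by 0.97 ± 0.07, the splicing regulator gene Celf3 by 0.96 ± 0.18, and Cntfr, the receptor gene for ciliary neurotrophic factor, by 0.96 ± 0.34. Plac9a and Xlr3b have near-identical copies, so their values are uncertain as to which copy was measured. Of the other genes among the 10 lowest, the chemokine gene Ccl9 fell by 1.05 ± 0.58, Arhgap22 by 0.99 ± 0.16, the matrix gene Thbs1 by 0.94 ± 0.70, the myeloid receptor gene Gpr84 by 0.93 ± 0.65 and the alarmin gene Il33 by 0.90 ± 0.78. For Mmp3 the values were -2.12, -2.37, -0.59 and -0.95 on arrays 1 to 4, and for Il33 they were -1.49, -1.65, -0.14 and -0.31.

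**Figure D1:**
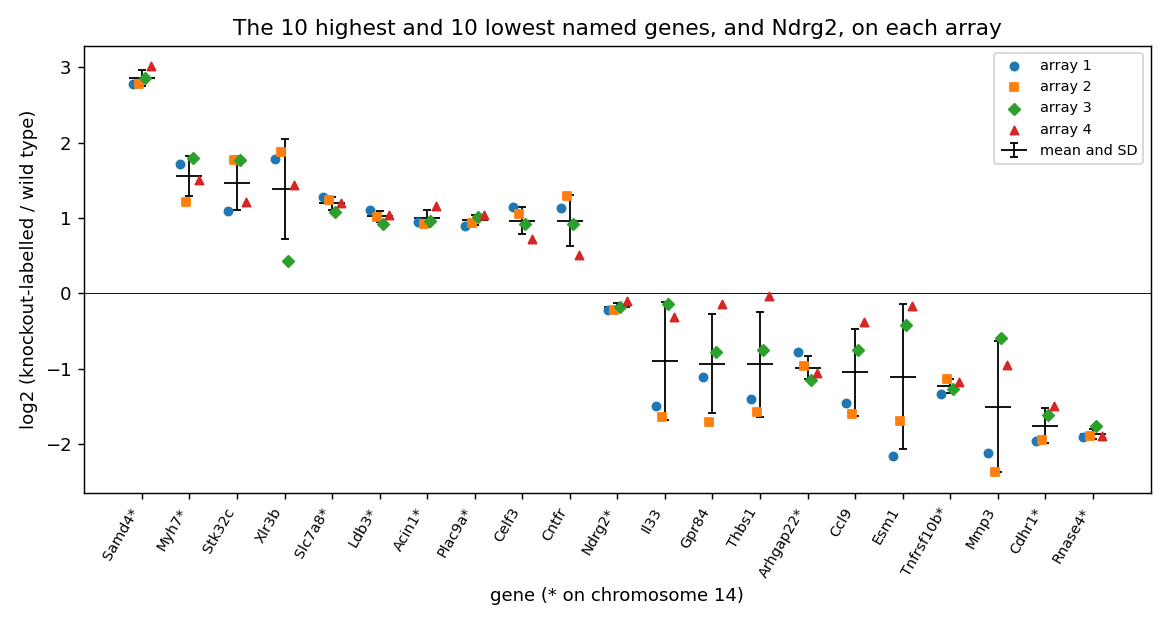
Log2 ratio of knockout-labelled over wild type (vertical axis) on each of the 4 arrays for the 10 highest and 10 lowest named genes and Ndrg2 (horizontal axis; stars mark genes on chromosome 14); bars give the mean and SD. Samd4 lies between 2.78 and 3.01 on all arrays, while Mmp3 lies between -2.37 and -0.59.

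Over all features tested, 2119 of 24565 were higher and 3111 lower in the knockout-labelled samples (limma, adjusted p under 0.05), and 9161 had an unadjusted p under 0.05. The changes were mostly small: the median size among those that passed was 0.23 on the log2 scale, or 1.18-fold, while 67 rose and 57 fell by at least 1.5-fold, and 9 rose and 6 fell by at least 2-fold. Samd4, Myh7, Rnase4, Cdhr1, Tnfrsf10b and 8 others of the 20 genes named above kept their calls in all 20 alternatives run for each, whereas Esm1 lost its call in 12, Il33 and Thbs1 in 10 each, Gpr84 in 8, Mmp3 in 5, and Ccl9 and Xlr3b in 2 each. The value of Esm1 ranged from -1.92 to -0.30 over them. For genes with a second kept probe that passed, the 2 brightest probes had the same sign in 685 of 1085 (63.1%), against 48.6% when probes were paired at random, and in 18 of 23 of those that changed by at least 1.5-fold. The second probe showed a median of 0.194 of the change of the first. Off chromosome 14 the signs were the same for 69.8% of higher and 59.6% of lower genes. On chromosome 14 they were the same in 32 of 53 genes that passed (60.4%). The number of calls moved by over 1.5 times with single arrays left out (lowest without replicate 2, with 807 higher and 1221 lower), with no replicate block (1263 and 1557) and with median centring in place of loess (6339 and 13148). The number of lower calls alone moved that far with the scanner software's log ratios, to 1751.

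The third question was where in the genome the changed genes lay relative to Ndrg2, since a targeted allele can carry flanking sequence of its strain of origin. Changes of at least 1.5-fold were concentrated on chromosome 14, which carries Ndrg2: 25 of its 596 tested genes (4.19%) passed by that much, against 0.69% or less on every other autosome and X. Samd4, Myh7, Slc7a8, Ldb3, Acin1 and Plac9a, 6 of the 10 highest genes, and Rnase4, Cdhr1, Tnfrsf10b and Arhgap22, 4 of the 10 lowest, were on it. The 25 genes split into 13 that rose and 12 that fell, and each had the same sign on all 4 arrays. So had 5210 of all 5230 features that passed. Only 4 of the 25 had a second kept probe, with the same sign in 3. With the scanner software's log ratios 24 of the 25 kept a change of at least 1.5-fold in the same direction, and with median centring 22, but there the share was 15.8% on chromosome 14 and up to 13.3% on another chromosome.

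**Figure D2:**
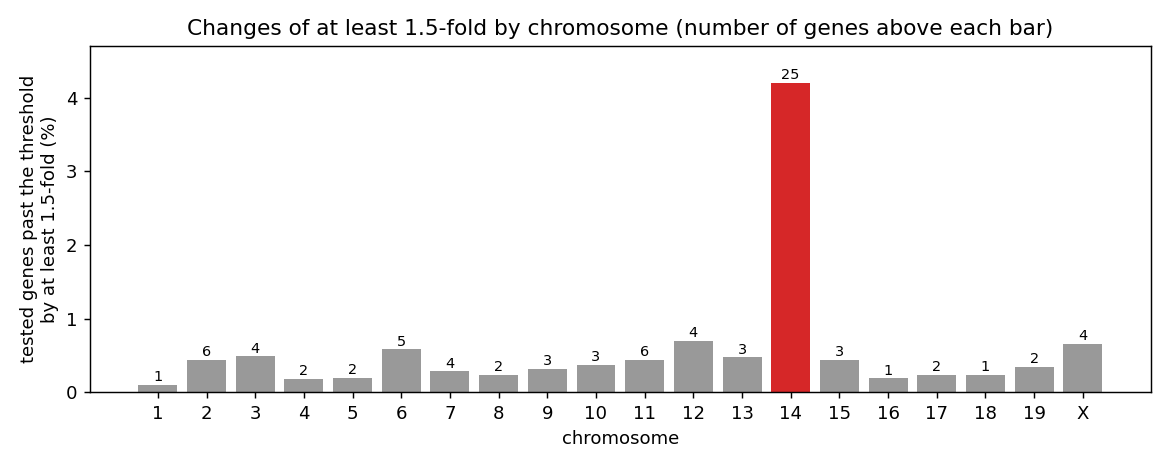
Percent of tested genes that passed the threshold by at least 1.5-fold (vertical axis) on each chromosome (horizontal axis), with the number of such genes above each bar. Chromosome 14 stands at 4.19% and the next highest, chromosome 12, at 0.69%.

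Within 2 Mb of Ndrg2, 19 of 36 tested genes passed, 9 higher and 10 lower. Beside Rnase4, those that fell included Rpgrip1 at -0.51 ± 0.03 (its second probe at -0.58), Supt16, a histone chaperone gene, at -0.50 ± 0.07, and Tep1 at -0.29 ± 0.05. Those that rose included Pnp2, a purine nucleoside phosphorylase gene, at 0.94 ± 0.09, its neighbour Pnp going the other way at -0.31 ± 0.25, and the angiogenin family genes Ang4 at 0.48 ± 0.03 and Ang at 0.41 ± 0.05. Close paralogs of Pnp2 and of the angiogenin genes could not be told apart by a probe whose sequence is unknown. Ang2 was not well above background in any wild-type channel. Its bound came out equal to the measured ratio, 1.25-fold higher in the knockout-labelled samples (limma, adjusted p = 0.00556). Ccnb1ip1 was not well above background in any knockout-labelled channel and was at least 1.29-fold lower (limma, adjusted p = 0.0137). Different probes disagreed for Arhgef40 (-0.20 and 0.52) and Tox4 (0.36 and -0.34). The chromatin remodeller gene Chd8 rose by 0.39 ± 0.08, and Ttc5, Pip4p1 and Mettl17 rose by 0.26 ± 0.08, 0.30 ± 0.12 and 0.25 ± 0.08. With median centring in place of loess, Chd8, Pip4p1 and Ccnb1ip1 turned the other way. Further falls were those of Rnase10 by 0.29 ± 0.11, Olfr738 by 0.35 ± 0.23 and Rab2b by 0.15 ± 0.06.

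**Figure D3:**
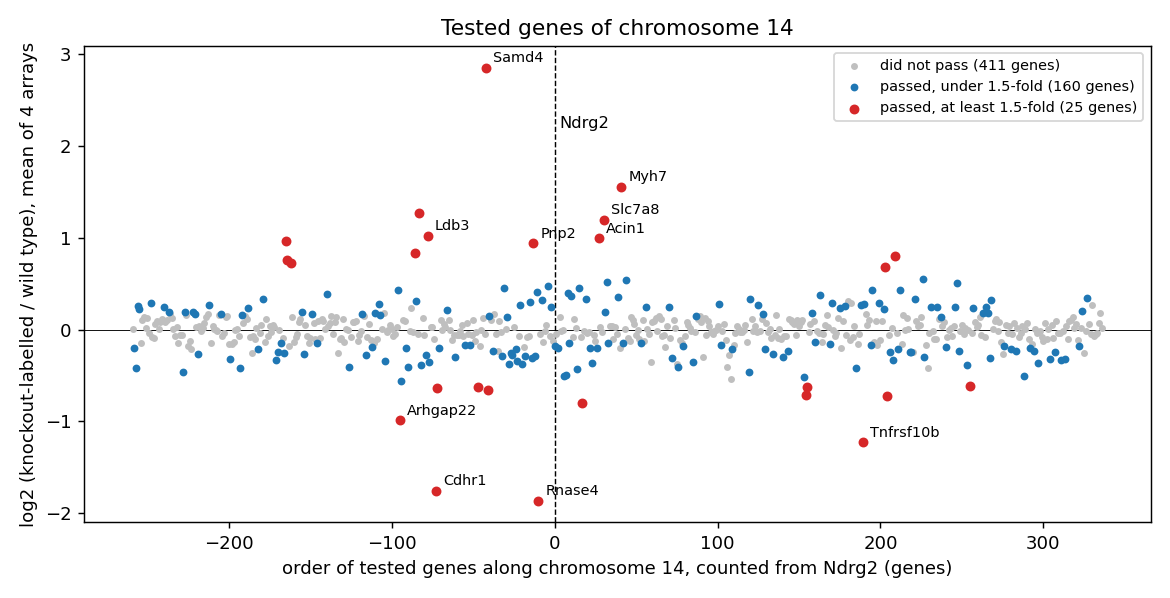
Mean log2 ratio of knockout-labelled over wild type over 4 arrays (vertical axis) for the 596 tested genes of chromosome 14 in their order from Ndrg2 (horizontal axis, dashed line at Ndrg2). Red points are the 25 genes that passed by at least 1.5-fold, from Samd4 at 2.86 to Rnase4 at -1.87.

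Within 10 Mb of Ndrg2, 64 of 189 genes passed (33.9%), against 3565 of 16826 elsewhere (21.2%), an odds ratio of 1.90 (95% interval 1.38 to 2.60; Fisher's exact test, two-sided, p = 7.27e-05). The odds ratio was 2.56 for 5 Mb and 4.14 for 2 Mb. For changes of at least 1.5-fold within 10 Mb, such as those of Samd4 and Rnase4, it was 11.3 (95% interval 4.90 to 23.1; Fisher's exact test, two-sided, p = 3.45e-07). These odds ratios compare each window with the rest of the genome, and their intervals take genes as independent. For changes of at least 1.5-fold the odds ratio of the whole of chromosome 14 was 12.4. Within the chromosome such changes were not densest beside Ndrg2. On the side of lower coordinates they made up 7.94% of genes within 10 Mb and 12.8% at 10 to 20 Mb. On the other side the shares were 3.17% and 6.74%. With median centring in place of loess the odds ratio over all calls was 0.945.

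The fourth question was whether gene groups fixed before the data were examined shifted together. Interferon-stimulated genes were lower as a list by camera with its preset correlation, but not with an estimated correlation or by fry (adjusted p = 0.873 and 0.374): 8 of 45 fell, 37 did not pass and none rose, with a median of -0.30, and 42 of the 45 lay below 0. The guanylate-binding protein genes Gbp2 and Gbp3 fell by 0.85 ± 0.70 and 0.71 ± 0.36, the interferon-induced GTPase gene Igtp by 0.52 ± 0.38, and the signal transducer gene Stat2 by 0.31 ± 0.22. With the preset correlation alone, 4 other lists were lower: neutrophil markers, complement genes, cytokines and chemokines, and reactive astrocyte genes; none of them passed with an estimated correlation or by fry.

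By limma's camera with its preset correlation, the interferon-stimulated list had an adjusted p of 0.00128 over the 32 lists, neutrophil markers of 0.0213, and complement genes, cytokines and chemokines and reactive astrocyte genes of 0.0294 each. With an estimated correlation all 5 had an adjusted p of 0.873. Of neutrophil markers, 4 of 22 fell and 18 did not pass, among the former Mcemp1 at -0.42 ± 0.08, the elastase gene Elane at -0.22 ± 0.06 and the receptor gene Csf3r at -0.25 ± 0.11. Of complement genes, 6 of 19 fell and 13 did not pass, with the receptor gene C3ar1 at -0.45 ± 0.18 and the protease gene C1ra at -0.38 ± 0.21, whose second probe stood at 0.037. Of cytokines and chemokines, 7 of 39 fell, 2 rose and 30 did not pass, with Cxcl3 at -0.47 ± 0.23 and Tgfb1 at -0.34 ± 0.18 beside Ccl9. Of reactive astrocyte genes, 5 of 36 fell and 31 did not pass, among them Cd44 at -0.34 ± 0.23 and Psmb8 at -0.35 ± 0.27. Adjusted over the list alone, 16 of the interferon-stimulated genes, 4 neutrophil markers, 7 complement genes, 11 cytokines and chemokines and no reactive astrocyte gene were lower.

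These lists differed between arrays. The median of the interferon-stimulated list was -0.23, -0.84, -0.05 and 0.01 on arrays 1 to 4, and that of cytokines and chemokines was -0.48, -0.57, -0.04 and 0.05. Lists outside the immune response were also lowest on arrays 1 and 2: erythrocyte genes had medians of -0.26, -0.60, -0.09 and 0.11, and striatal and other subcortical markers of -0.22, -0.37, 0.06 and -0.08. Without replicate 2 the adjusted p of the interferon-stimulated list was 0.110 by camera and no list passed; without replicate 1, 1 list passed as lower, without replicate 3, 18, and without replicate 4, 13.

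**Figure D4:**
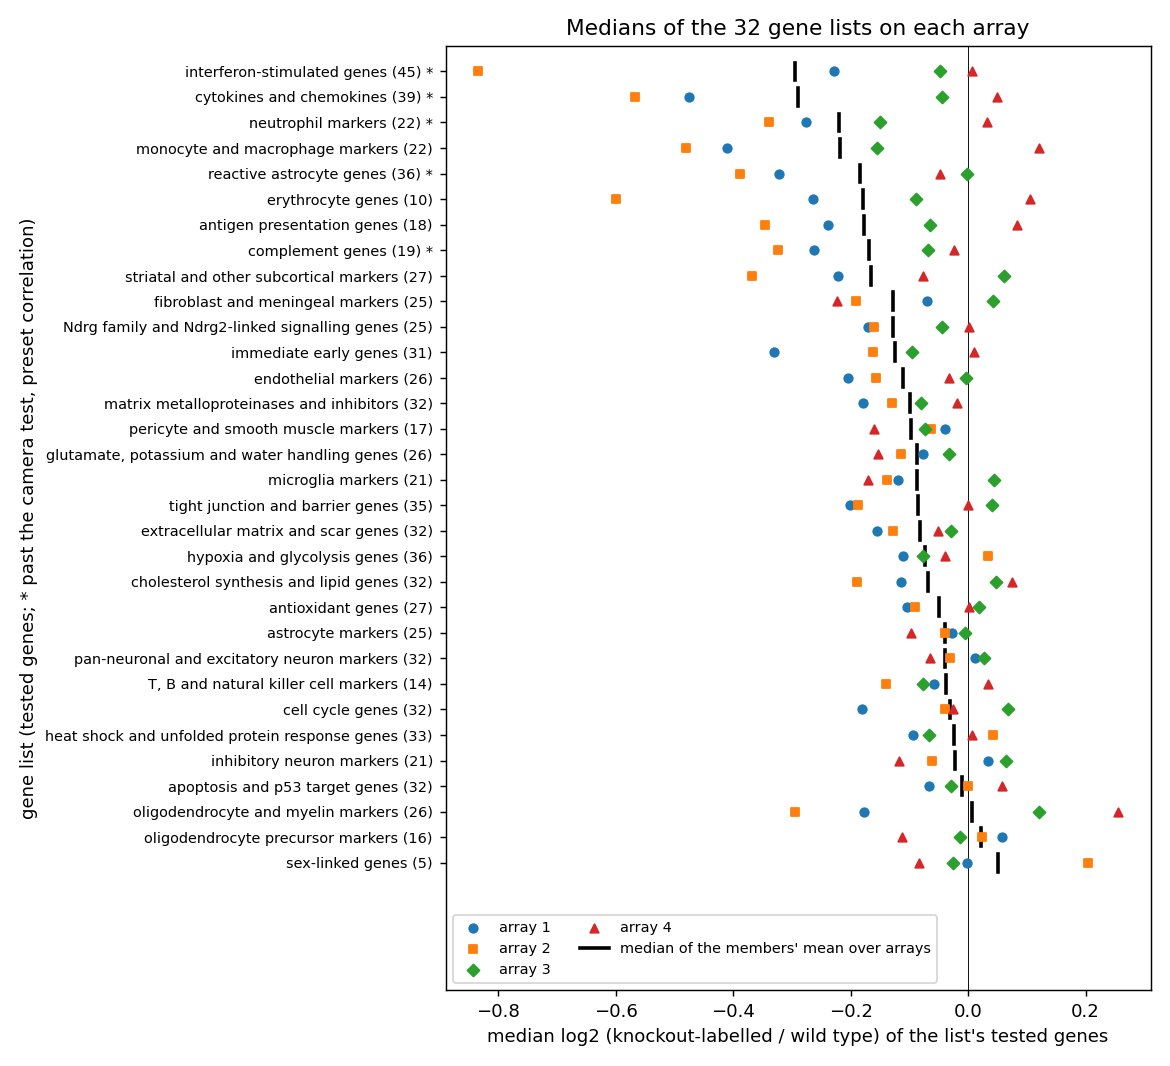
Median log2 ratio of knockout-labelled over wild type (horizontal axis) of the tested genes of each of 32 lists (vertical axis, tested genes in brackets) on each of 4 arrays, with the median over the members' means as a black bar. The interferon-stimulated list ranges from -0.84 on array 2 to 0.01 on array 4.

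Among the lists of cell type markers, only neutrophil markers passed camera with the preset correlation, and none with an estimated correlation or by fry. Of astrocyte markers, 5 of 25 fell, 20 did not pass and none rose: the glycolytic gene Aldoc, which is among the very bright features that were lower as a set, at -0.39 ± 0.09, the water channel gene Aqp4 at -0.41 ± 0.17, the glutamate transporter gene Slc1a2 at -0.30 ± 0.09, and Glul and Ranbp3l, both chosen after their values were seen, at -0.25 and -0.24. The list's median was -0.04 (camera, adjusted p = 0.326), and adjusted over the list alone the same number, 5, were lower. Of microglia markers, 8 of 21 fell and 13 did not pass, with Ctss at -0.45 ± 0.11, the fractalkine receptor gene Cx3cr1 at -0.29 ± 0.06 and Olfml3 at -0.25 ± 0.09 (camera for the list, adjusted p = 0.0774; 10 lower adjusted over the list alone). Of monocyte and macrophage markers, 3 of 22 fell: Ms4a4c at -0.49 ± 0.09, Adgre1 at -0.40 ± 0.14 and Itgam at -0.24 ± 0.09 (adjusted p for the list 0.0774). Other probes of these genes often showed less. They stood at -0.09 for Adgre1, -0.03 and -0.18 for Itgam, and -0.19 and -0.33 for Ms4a4c, with SDs of 0.48 and 0.79. Those of Cx3cr1 and Olfml3 stood at -0.09 and -0.42, that of Aqp4 at -0.31, and those of Slc1a2 at -0.08 and -0.46. The probe used for Ms4a4c had a mean log2 intensity of 14.6, against 6.88 and 6.95 for its other probes. For Itgam the values were 14.9, against 7.40 and 8.62. Whether the probes of each of these 2 genes measured the same transcript was not tested. Of T, B and natural killer cell markers, 1 of 14 fell, Nkg7 at -0.23 ± 0.05, and the list's median was -0.04.

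Matrix metalloproteinases and their inhibitors, which act on the vessel wall after ischaemia, went both ways: 3 of 32 fell, 2 rose and 27 did not pass. Mmp3 and Mmp11 (-0.25 ± 0.09) fell, though a second probe of Mmp11 stood at -0.09. Mmp14, a membrane-bound protease gene on chromosome 14, rose by 0.34 ± 0.20. The gelatinase gene Mmp9, chosen after its value was seen, did not pass at -0.13. Of tight junction and barrier genes, 5 of 35 fell and 1 rose, with the junction gene Tjp1 at -0.25 ± 0.10 and Angpt1 at -0.28 ± 0.13, and of endothelial markers 5 of 26 fell and 1 rose, with Ly6a at -0.49 ± 0.35 and Pltp at -0.38 ± 0.12. Neither list passed by camera (adjusted p = 0.09995 and 0.128). Of genes linked to Ndrg2 and its signalling, 7 of 25 fell and 2 rose; Bmp4, on chromosome 14, fell by 0.63 ± 0.11. Adjusted over the list alone, 2 matrix metalloproteinase genes were lower and 2 higher, 5 and 1 barrier genes, 7 and 1 endothelial markers, and 8 and 2 genes linked to Ndrg2; 3 monocyte and macrophage markers and 1 T, B or natural killer cell marker were lower.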

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

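All tests in this part were chosen after the results were seen, except the sign patterns of the arrays, and no test used samples outside the comparison.

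In 7 of 129 named genes, 1 array stood apart from the other 3, with a gap to its nearest neighbour over the whole range above Dixon's critical value for 4 samples; chance alone gives about 1 in 20, or 6.45 here. Birc5, a mitosis gene, had a ratio of 0.988 with 0.43 on array 2 against a mean of 0.17 on the others. Nkg7 had 0.905 (array 1, -0.15 against -0.25), Rnase4 0.888 (array 3, -1.76 against -1.90) and Mcm4 0.888 (array 1, -0.24 against -0.15). Adgre1 had 0.866 (array 2, -0.18 against -0.47), Stat2 0.860 (array 2, -0.63 against -0.20) and Acin1 0.836 (array 4, 1.16 against 0.94).

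The clearest pattern was the concentration of large changes on chromosome 14, led by Samd4, Myh7, Rnase4 and Cdhr1. Dye effects of single probes would lie anywhere in the genome, but the odds ratio of changes of at least 1.5-fold on chromosome 14 against the other chromosomes was 12.4 (95% interval 7.35 to 20.2). It was 6.75 with the scanner software's log ratios and 1.57 (1.24 to 1.97) with median centring, the lowest of all alternatives. The intervals take genes as independent, whereas some neighbours moved together. Examples chosen after their values were seen are Plac9a, Tmem254a and Duxbl2, at 0.97, 0.76 and 0.72. The intervals may therefore be too narrow. Sequence differences under the probes would lower the signal, whereas 13 of the 25 genes rose. For the 12 that fell, such differences stay open because no probe sequence was at hand to search. A candidate explanation is flanking DNA of another origin carried with the targeted allele, but the genes' median distance from Ndrg2 of 14.8 Mb, against 18.6 Mb for random genes of the chromosome, gave a one-sided permutation p of 0.161. That missed the bound of 0.05 set before this p was computed. It is read here as undecided, a reading made after p was seen. The reason is that a long segment, such as 30 Mb on either side, would hold 442 of the 595 other genes tested on the chromosome. All 25 large changes lay within those 30 Mb, against 0 among the 153 genes beyond (Fisher's exact test, two-sided, p = 0.000713). Of the genes beyond, 23.5% passed at any size, against 21.0% of genes on the other chromosomes. The 30 Mb bound was chosen after the values were seen, so this p cannot decide the question. An effect of Ndrg2 loss on single genes within the segment was not tested.

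The second pattern was the near-normal Ndrg2 signal. The same genotype in both channels is argued against by the share of chromosome 14 genes that changed by at least 1.5-fold. It was 4.19%, against at most 0.693% on another chromosome, and with median centring 15.8%, against at most 13.3%. All 25 of these genes with loess had the same sign on all 4 arrays. So had 5210 of the 5230 features that passed, so the shared sign adds no support. Divided by the flattest slope of the spike-ins, the log2 ratio of Ndrg2 would be -0.25 with loess but -1.11 with median centring, a setting in which 200 features of like intensity not placed on chromosome 14 had a median of -0.65. Ratio compression is argued against relative to those features, where the divided value was -0.23 with loess and -0.22 with median centring and, less 2 SD of the features, stayed at -0.69 in both, short of the 4-fold loss (-2) it would have to hide. A probe outside the deleted part of the transcript, with a transcript still made from the allele, may account for a signal 769 times the background; this stays open without the probe sequence and the allele's structure.

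The third pattern was the lower interferon and immune lists, with Gbp2, Gbp3, Igtp and Stat2 in front, which held with the preset correlation alone: with an estimated correlation each of the 5 lists had an adjusted p of 0.873, and fry called 0 lists. Fixed dye effects of the probes would be alike on all arrays, but the median of the interferon-stimulated list ranged over 0.842 between arrays, with 44 of 45 members lower on array 2 than on array 4, and second probes had the same sign in 10 of 10 genes. Differences between the paired samples in the extent of injury cannot be told apart from genotype: arrays 1 and 2 alone gave 19 lower lists and arrays 3 and 4 alone gave 0, erythrocyte genes (-0.26, -0.60, -0.09 and 0.11 on arrays 1 to 4) and striatal and other subcortical markers (-0.22, -0.37, 0.06 and -0.08) were also lowest on arrays 1 and 2, and nothing in the labels gives the size of the injury. Fewer blood-borne leukocytes in the knockout-labelled samples would lower markers of all of them by about as much. The medians of neutrophil markers and of monocyte and macrophage markers were both -0.22, which goes with that. The median of T, B and natural killer cell markers was -0.038, which does not, but only 14 of its 23 members were tested. The outcome set against this explanation, a median above 0 by more than the spread of the members, was not met either, so it stays open.

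With 8 sign patterns of the 4 arrays, no share under 0.05 can be reached, so whether chance is excluded cannot be decided this way. The real orientation gave 5230 calls, 124 of them of at least 1.5-fold, and an odds ratio of 1.90 near Ndrg2, and in each of these 3 cases 1 of the 8 patterns gave as much, with 0 calls in the highest other. For gene lists 6 of the 8 gave as many as the real 5, and the highest other gave 20, 4 times the real number, which points to members of a list moving together between arrays.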

How the results depend on the processing

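Median in place of mean spot signals, leaving out the chromosome 14 genes, arrays 1 and 2 only, arrays 3 and 4 only, and leaving out features with a mean log2 intensity above 16 were chosen after the data were seen; all other alternatives were planned. The base-composition correction was not run, as no probe sequences were given. The cause of the changes below was not tested, except that fewer arrays leave fewer degrees of freedom and a stricter or looser threshold changes counts by construction. Median centring moved the median over all features from -0.02 to -0.18. Higher and lower calls, 2119 and 3111, became 6339 and 13148 with median centring, 1263 and 1557 with no replicate block, 67 and 57 at 1.5-fold or more, 490 and 708 at an adjusted p under 0.01, 3199 and 4681 under 0.1, and 689 and 1090 on arrays 3 and 4 only; the lower calls became 1897 with normexp offset 0, 1751 with the scanner software's log ratios and 1751 with the series matrix values. Leaving out each array gave 807 to 1262 higher and 1221 to 1917 lower calls. Ndrg2 stayed below 0 throughout, at -0.81 with median centring (adjusted p = 6.71e-06), -0.17 with offset 0 (adjusted p = 0.0589), -0.043 with the scanner software's log ratios and the series matrix values, -0.15 on arrays 3 and 4 only, and -0.21 to -0.17 with each array left out, calls lost in all of these but with median centring and without replicate 4. The odds ratio near Ndrg2 was 0.945 with median centring and stayed above 1 and past the test in the other 25 alternatives. Aquantile left the log ratios unchanged, and the series matrix repeated the scanner software's ratios. The alternatives counted here and in the Results therefore hold repeats. Without the chromosome 14 genes 2034 were higher and 3012 lower. Mean correlation between arrays, 0.523, was 0.870 with median centring and 0.730 on arrays 1 and 2 only. Second probes had the same sign in 63.1% of calls, 74.0% with median centring, 91.0% with the mean of all probes (which shares the second probe by construction), 74.2% on arrays 1 and 2 only and 63.3 to 68.7% with each array left out. Lists lower, 5 by camera, were 12 with median centring, 15 with no filter, 2 with array weights, 1 with the scanner software's log ratios, 1 with the series matrix values, 1 with no replicate block, 0 with an estimated correlation, 0 by fry, 19 on arrays 1 and 2 only, 0 on arrays 3 and 4 only and 0 to 18 with each array left out; lists higher, 0, were 1 with median centring and 1 on arrays 3 and 4 only. Results that turned were reactive astrocyte genes (0.0013) and complement genes (0.0070) on arrays 3 and 4 only, oligodendrocyte markers (-0.25) on arrays 1 and 2 only, Arhgef40 (0.16) with the mean of all probes, and, with median centring, T, B and natural killer cell markers (0.21), Ccnb1ip1 (0.21), Chd8 (-0.033), Mal (-0.21), Ndrg1 (-0.25), Nefm (-0.11), Olig2 (-0.087), Pip4p1 (-0.0035) and Xist (0.46). Over all named genes but Ndrg2 and their alternatives, 2085 values kept their direction and side of the threshold or did not pass in either, 446 lost their call, 16 gained one and 9 turned; for lists the numbers were 570, 41, 57 and 4. Signal over background limits the bounds of Ang2, Ccnb1ip1 and Xist.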

Other observations

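The lists described here were fixed before the data were examined, and no explanation was tested for them. Neuronal markers went both ways. Of 32 pan-neuronal and excitatory markers, 2 rose and 3 fell. The neurofilament gene Nefm, on chromosome 14, stood at 0.26 ± 0.04 and the synapsin gene Syn1 at -0.23 ± 0.07 (SD, n = 4). Of 21 inhibitory markers, 2 rose and 4 fell, with Dlx1 at 0.38 ± 0.08 and the neuropeptide gene Cck at -0.52 ± 0.19. Of oligodendrocyte and myelin markers, 3 of 26 rose, among them Mal at 0.39 ± 0.19, and 2 fell, Sox10 at -0.49 ± 0.41 and Bcas1 at -0.42 ± 0.34; the list's median ran from -0.29 on array 2 to 0.26 on array 4. Of oligodendrocyte precursor markers 1 of 16 rose, Olig2 at 0.16 ± 0.04, and 1 fell, Sox10. Mal, Nefm and Olig2 turned below 0 with median centring in place of loess. Striatal and other subcortical markers had a median of -0.16 with 4 of 27 lower and 1 higher, with Tac1 at -0.51 ± 0.28. Of erythrocyte genes 2 of 10 fell, Hba-a2 at -0.46 ± 0.35 and Hemgn at -0.44 ± 0.11. Fibroblast and meningeal markers (6 of 25 lower, 1 higher) included the matrix gene Lum at -0.51 ± 0.31, and pericyte and smooth muscle markers (2 of 17 lower) included Mcam at -0.43 ± 0.10. A second probe of Mcam stood at -0.13 (SD 0.27).

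Among stress and metabolic groups, 9 of 36 hypoxia and glycolysis genes fell and 5 rose. Hk1 (-0.50 ± 0.09), Eno1 (-0.45 ± 0.05) and Gapdh (-0.40 ± 0.07) fell on their brightest probes, while a second probe of Hk1 stood at 0.10 and 6 other probes of Gapdh between -0.25 and 0.22. Metallothionein genes Mt1 and Mt2 fell by 0.61 ± 0.29 and 0.50 ± 0.20 within the antioxidant list, of which 7 of 27 fell and 1 rose. The cell death gene Bax rose by 0.51 ± 0.08 in the apoptosis and p53 list, where 3 of 32 rose and 7 fell. Of immediate early genes 7 of 31 fell and none rose, with Jund at -0.35 ± 0.15 and Bdnf at -0.34 ± 0.18. Heat shock and unfolded protein response genes (2 of 33 lower) included Chac1 at -0.51 ± 0.26 and Atf4 at -0.34 ± 0.07, whose second probe stood at 0.029. Cell cycle genes (3 of 32 lower, 1 higher) included Tyms at -0.29 ± 0.08. Genes of glutamate, potassium and water handling (7 of 26 lower) included Grm3 at -0.27 ± 0.05. Cholesterol and lipid genes (6 of 32 lower, 4 higher) included Lpl at -0.48 ± 0.25 and Abca1 at -0.28 ± 0.06. Extracellular matrix and scar genes (6 of 32 lower) included Fbn1 at -0.46 ± 0.09 and Itga5 at -0.48 ± 0.19, and antigen presentation genes (4 of 18 lower) included H2-Ab1 at -0.64 ± 0.53. Adjusted over the list alone, 11 hypoxia and glycolysis genes were lower and 6 higher, 10 and 3 antioxidant genes, 7 and 5 apoptosis and p53 genes, 8 and 1 antigen presentation genes, 8 and 0 immediate early genes, and 5 and 3 inhibitory neuron markers. The counts became smaller for pan-neuronal and excitatory markers, 2 lower and 2 higher, and for cell cycle genes, 2 lower and 1 higher. They also did for pericyte and smooth muscle markers, 1 lower, and oligodendrocyte precursor markers, 0 lower and 0 higher. By camera none of the lists in these paragraphs passed, and their smallest adjusted p was 0.0774.

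Median, mean and camera direction differed in sign for pan-neuronal, inhibitory neuron, oligodendrocyte, oligodendrocyte precursor, apoptosis and sex-linked lists. Of sex-linked genes, the Y-linked Ddx3y (0.10 ± 0.22), Uty (0.09 ± 0.11) and Kdm5d (0.05 ± 0.21) did not pass and Eif2s3y fell by 0.24 ± 0.10. Xist was not well above background in any knockout-labelled channel and was at least 1.14-fold lower there (adjusted p = 0.0495), but turned higher with median centring. Among the 322 features with a mean log2 intensity above 16, such as Mt1, Mt2, Gapdh, Eno1, Cck, Aldoc and Ndrg4, 176 were lower and 6 higher, with a median of -0.19, against a median of -0.02 for the 24243 others; this was examined after the values were seen.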
